A study of Mus musculus with 15 samples.

How the data were processed

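Gene expression was measured with 15 Affymetrix single-colour arrays hybridised with biotinylated cRNA made from mRNA of mammary epithelial cells. The cells came from digested glands of female C57BL/6 mice that had been injected with PBS, 5-azacytidine (AzaC) or valproic acid (VPA). The deposited table holds 22690 probe sets with 2 decimals. Its values range from 0 to 14.48, and between 2.29 and 2.59% of the probe sets of each array are listed at exactly 0. The values were taken as the authors' processed log2 signals, because as powers of 2 they span the usual range of Affymetrix intensities. Neither the base of the logarithm nor the summary, background and normalization methods are stated. The array medians lay between 7.22 and 7.47 and the interquartile ranges between 3.73 and 4.05, so the arrays had been brought to a common scale. By a rule fixed in advance, the values were then used as deposited.

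Groups, comparisons, tests, gene lists, the choice of genes to name and all alternatives but 3 were fixed before the data were examined. The arrays fall into 6 groups, from 2 stages in the labels and 3 injections, and 11 comparisons were made between them. Probe sets were assigned to gene symbols with the platform annotation of 2016: 20380 carried a single symbol, 691 carried several and 1619 carried none, among them 64 control probe sets. Probe sets without a single symbol were left out, and each of the 12393 genes was represented by the probe set with the highest mean over all arrays. No filter on dim genes was applied. No genome was at hand, so genes are given by symbol without coordinates.

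A linear model with a mean for each group was fitted to all 15 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3. Moderated tests were two-sided, with 9 residual and 2.31 prior degrees of freedom. P-values were adjusted by the method of Benjamini and Hochberg over all genes, with a threshold of 0.05. The dependence of a drug effect on the stage was tested as the difference between the pregnant and the virgin fold change. Changes are on the log2 scale with their standard errors (SE), and group means are given with standard deviations (SD). The fit was tested on simulated data with 100 changed genes per size. For AzaC in arrays labelled pregnant, 39 genes changed by 1 and 90 genes changed by 2 on the log2 scale were recovered. There, 9 unchanged genes passed the threshold. The changed genes were drawn from those with a mean over 6.43, and genes varied independently without a floor at 0. Recovery among dim genes was therefore not tested.

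A total of 34 gene lists on secretion, metabolism, stress, signalling, chromatin and cell types were tested against all other genes with camera of limma, with a preset correlation between genes of 0.01, adjusted over the lists of each comparison. At least 4 measured members were required, which all lists had. The list called immediate early genes below was drawn up for the response to tissue dissociation too. It includes heat shock genes and Socs3. The same test with a correlation estimated from the data was run beside it. A list that camera called is described by the median change of its members and by how many of them passed the threshold on their own.

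Genes were named by rule. In each comparison these were the 6 largest rises and the 6 largest falls among genes past the threshold whose replicates did not overlap between the groups, or the 3 smallest p-values in a direction with fewer than 3 passing. In each called list up to 3 passing members with the largest change were added, or the 2 members with the smallest p. A fixed set of 14 genes was added in every comparison, of which Prlr is not measured. Not every gene chosen by these rules is described below, and Elf5, Esr1, Pgr, Krt8, Krt14, Cdkn1a and Igf2 are among those left out. Clone and predicted gene names were skipped among the rises and falls.

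Alternatives fixed in advance were quantile normalization, leaving out genes with a mean under 6.43, the mean of all probe sets of a gene, eBayes with trend and robust settings, fitting only the arrays compared, the replicate number as a block, a minimum change of 1.5-fold, and leaving out each array in turn. Pseudocounts apply to linear values and were not run. After the data were seen, 3 more were chosen: the difference between 3' and 5' control probe sets as a covariate for RNA quality, leaving out the 3 arrays where the Gapdh difference was highest, and a floor at 5. Replicate numbers were checked for pairing: correlations of deviations between arrays of the same number ranged from -0.409 to 0.495 across genes, so the numbers were not used to pair arrays. The overlap between AzaC and VPA was compared with 50 simulated tables in which the drugs had no effect but the PBS arrays were shared. A further 20 such tables were made for each array left out. Genes varied independently in all these tables, while genes of the arrays vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.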

Results

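Transcripts of mammary epithelial cells were measured on 15 arrays. The labels give a stage, virgin at 9 weeks or pregnant at day 21, and an intraperitoneal injection. The injections were PBS as the control, AzaC, an inhibitor of DNA methylation, and VPA, an inhibitor of histone deacetylases. Arrays labelled pregnant comprise 2 with PBS, 3 with AzaC and 3 with VPA, and those labelled virgin comprise 2 with PBS, 3 with AzaC and 2 with VPA. The labels do not say whether replicates came from separate mice, so the p-values measure the spread between these samples, and the small number of arrays limits the precision. Replicates of a group correlated at 0.948 to 0.979 and other pairs of arrays at 0.922 to 0.978 across genes, which are not independent replicates. On the first principal component, which held 52.9% of the variance of genes with a mean over 6.43, the 6 drug arrays labelled pregnant lay between 15.3 and 44.0. The PBS arrays labelled pregnant lay at -28.2 and -32.1, and the arrays labelled virgin between -33.1 and 8.73.

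Milk-protein transcripts stood at the top of the scale on every array, whatever its stage label. Csn2 (beta-casein), Wap (whey acidic protein), Lalba (alpha-lactalbumin), Csn1s1 (an alpha-casein) and Glycam1, a mucin-like milk component, read at least 13.41 and were above the 99.5th percentile of genes on all 15 arrays. Mean Csn2 was 13.74 ± 0.08 (SD, n = 2) with PBS in arrays labelled virgin and 13.74 ± 0.07 (SD, n = 2) in those labelled pregnant. In all, 20 of 27 measured genes of milk proteins and secretory differentiation had a mean over 13.

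**Figure D1:**
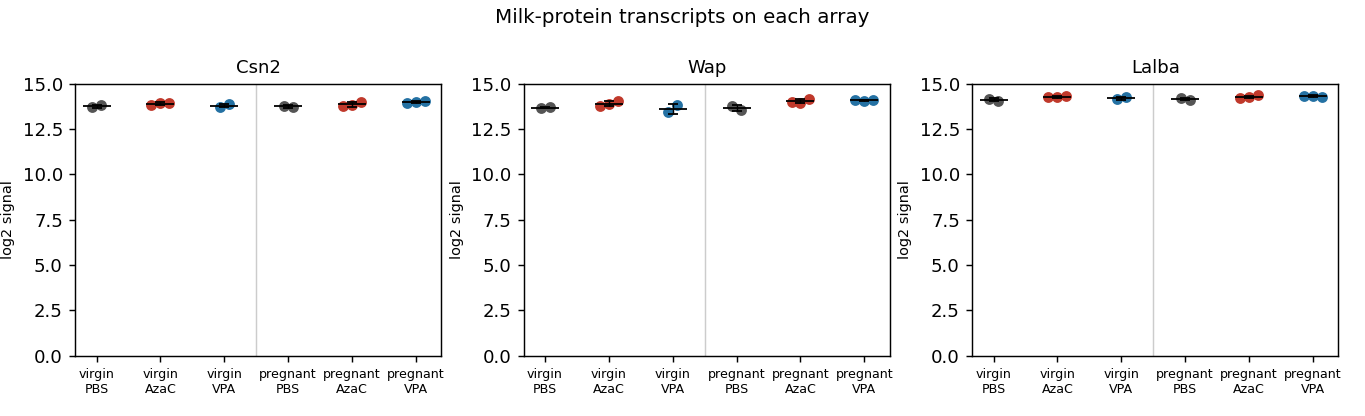
Log2 signal of Csn2, Wap and Lalba on each of the 15 arrays (points), by stage label and injection, with group means and SD (bars). All points lie at the top of the scale, where a difference may not register, with Csn2 group means between 13.74 and 13.97. Wap reads 13.60 with VPA in virgin and 14.08 with VPA in pregnant.

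The comparison of arrays labelled pregnant and virgin after PBS shows what differed between the stage labels without a drug. Mst1r, the receptor of macrophage-stimulating protein, was the 1 gene of 12393 past the threshold (adjusted p = 0.0167): it read 2.07 ± 0.03 (SD, n = 2) in arrays labelled pregnant and was listed at 0 on both arrays labelled virgin. It was listed at 0 on 11 of all 15 arrays. Csn2, Wap and Lalba, at the top of the scale, differed by -0.01, -0.02 and 0.05. The proliferation marker Mki67 differed by -0.16, the maintenance DNA methyltransferase Dnmt1 by 0.14 and the histone deacetylase Hdac1 by 0.08. Arntl, a clock transcription factor, differed by 1.26 (adjusted p = 0.222) and Mpp3, a membrane scaffold protein, by -1.49 (adjusted p = 0.443). The salivary gene Smr3a differed by -9.37 (adjusted p = 0.611), and its values in arrays labelled virgin read 10.85 ± 3.16 (SD, n = 2). Camera called 8 lists, in none of which a member passed. Ribosomal proteins (median 0.23, adjusted p = 0.000187) and the unfolded protein and stress response (0.14, adjusted p = 0.0364) were higher with the pregnant label. Markers of endothelial cells (-0.28, adjusted p = 0.000187), adipocytes (-0.42, adjusted p = 0.0014) and fibroblasts (-0.26, adjusted p = 0.0104) were lower. So were interferon-stimulated genes (-0.31, adjusted p = 0.000397), fatty acid oxidation (-0.21, adjusted p = 0.013) and extracellular matrix (-0.20, adjusted p = 0.013). With an estimated correlation the adjusted p of these lists lay between 0.672 and 0.791.

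The stage difference with PBS rested on single arrays. Without virgin PBS replicate 1, all 8 list calls ended (adjusted p from 0.462 to 0.774) and 22 genes passed. Without pregnant PBS replicate 1 (3 genes), endothelial markers reached 0.193, extracellular matrix 0.150 and the unfolded protein response 0.0508. Without pregnant PBS replicate 2 (4 genes), fatty acid oxidation reached 0.377 and the unfolded protein response 0.124, and without virgin PBS replicate 2 the latter reached 0.117. The unfolded protein response also reached 0.173 after quantile normalization. The Mst1r call ended without either pregnant array (0.0756 and 0.0715) and without virgin PBS replicate 2 (0.0713), over a range of adjusted p up to 1 among its alternatives.

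AzaC was compared with PBS in the arrays labelled virgin, which carried milk-protein transcripts at the top of the scale like those labelled pregnant. Socs3, a feedback inhibitor of cytokine signalling, read 8.61 ± 0.14 (SD, n = 3) with AzaC and 6.91 ± 0.04 (SD, n = 2) with PBS, a difference of 1.71 ± 0.29 (SE, adjusted p = 0.221). Arntl differed by 1.19 (adjusted p = 0.172), Taf7l, a testis-expressed transcription factor subunit, by -2.42 (adjusted p = 0.263) and Mmp8, a neutrophil collagenase, by -1.58 (adjusted p = 0.349). No gene passed with limma (0 of 12393), and 849 had an unadjusted p under 0.05. Every other setting that kept all arrays gave 0. The AzaC arrays labelled virgin were spread widely, with replicate 1 at -33.1 on the first principal component and replicates 2 and 3 at 2.36 and 8.73. Of genes called with AzaC in arrays labelled pregnant, chosen here after their values were seen, Kit read 7.26 on virgin AzaC replicate 1, 10.41 on replicate 2 and 9.98 on replicate 3, against 9.11 and 6.74 with PBS. Angptl4 read 9.06, 11.66 and 12.28 on the same 3 arrays, against 10.16 and 8.25 with PBS. Leaving out virgin AzaC replicate 1 likewise gave 0 genes. Genes of the cell cycle and DNA replication were lower as a list, with a median of -0.62 over 43 genes and 0 members past the threshold (adjusted p = 2.56e-07, 0.738 with an estimated correlation). Fatty acid oxidation genes were higher (median 0.39, adjusted p = 0.000919), as were immediate early genes (0.48, adjusted p = 0.00334), and both calls ended without virgin PBS replicate 2 (0.122 and 0.191) and with an estimated correlation (adjusted p = 0.738 for each). Of the 7 other lists called, luminal epithelium (0.29, adjusted p = 0.0108), ribosomal proteins (0.16, adjusted p = 0.00334) and histone deacetylases and acetyltransferases (0.29, adjusted p = 0.0158) were higher. Markers of neutrophils (-0.26, adjusted p = 0.00334), fibroblasts (-0.25, adjusted p = 0.0112), germline genes (-0.23, adjusted p = 0.0142) and polycomb targets (-0.17, adjusted p = 0.0158) were lower. With an estimated correlation the adjusted p of these 7 lists lay between 0.398 and 0.778. Those 7 calls all ended without virgin PBS replicate 1 (adjusted p from 0.150 to 0.953), and 5 of them ended after quantile normalization (from 0.0583 to 0.206). Without virgin AzaC replicate 1 fibroblasts reached 0.487, without replicate 2 luminal epithelium reached 0.0673 and polycomb targets 0.0763. Without replicate 3 luminal epithelium, deacetylases, germline genes and polycomb targets reached 0.101, 0.118, 0.0783 and 0.0622. The count of genes became 33 without virgin PBS replicate 1, 5 without replicate 2 and 1 without virgin AzaC replicate 2.

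VPA in arrays labelled virgin gives the matching comparison for the deacetylase inhibitor. Fgf10, a growth factor of the mammary stroma, fell by 2.15 ± 0.22 (SE), from 5.18 ± 0.11 (SD, n = 2) to 3.03 ± 0.38 (SD, n = 2), and was the 1 gene past the threshold (adjusted p = 0.0109; 851 genes with an unadjusted p under 0.05). Armh4, a membrane protein, differed by 2.21 (adjusted p = 0.0778) and the interleukin receptor gene Il9r by -2.10 (adjusted p = 0.155). Camera called fibroblast markers (median -0.62, adjusted p = 4.24e-05), extracellular matrix (-0.31, adjusted p = 0.00232), interferon-stimulated genes (-0.24, adjusted p = 0.00843), polycomb targets (-0.13, adjusted p = 0.0219), imprinted genes (-0.14, adjusted p = 0.0301) and adipocyte markers (-0.38, adjusted p = 0.0301) lower. Oxidative phosphorylation (0.23, adjusted p = 0.0013) and ribosomal proteins (0.14, adjusted p = 0.0116) were called higher. No member of these 8 lists passed, and their adjusted p with an estimated correlation lay between 0.362 and 0.839. All 8 calls ended without virgin PBS replicate 1 (from 0.491 to 0.967), where 39 genes passed. Without virgin VPA replicate 2, 12 genes passed and 7 of the calls ended, fibroblast markers at 0.0876 among them. Polycomb targets and adipocytes reached 0.194 and 0.159 without virgin VPA replicate 1. Fgf10 lost its call without virgin PBS replicate 2 (0.0706) and without virgin VPA replicate 1 (0.0803). At a floor of 5 its change was -0.19 (0.750), over a range of adjusted p up to 0.840.

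AzaC in arrays labelled pregnant was accompanied by much larger differences: 466 genes rose and 472 fell. Cyp51, which removes a methyl group from lanosterol, fell by 3.24 ± 0.50 (SE, adjusted p = 0.010), and the sterol pathway enzymes Idi1 and Fdps fell by 2.94 ± 0.44 (SE, adjusted p = 0.010) and 2.75. In all, 9 of 19 measured cholesterol synthesis genes fell and 0 rose. The desaturase Scd2 fell by 2.29 and the acetyl-CoA synthetase Acss2 by 2.08, among 9 of 24 genes of fatty acid and triglyceride synthesis that fell. In contrast, Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 4.91 ± 0.80 (SE, adjusted p = 0.0115), the dehydrogenase Acadl by 2.20 and the mitochondrial carrier Ucp3 by 2.12 ± 0.38 (SE, adjusted p = 0.0135). They were among 6 of 23 fatty acid oxidation genes that rose. Uhrf1, which guides Dnmt1 to newly copied DNA, fell by 3.61 ± 0.92 (SE, adjusted p = 0.0374), Dtl, a replication licensing ligase subunit, by 3.22 ± 0.61 and the licensing factor Cdc6 by 2.68 ± 0.50. Of 43 measured genes of the cell cycle and DNA replication, 11 fell, Cdc6 among them, and Mki67 was at -3.62 ± 1.03 (SE, adjusted p = 0.0544). Socs3 had the smallest p: it rose by 3.62 ± 0.29 (SE), from 6.66 ± 0.19 (SD, n = 2) to 10.27 ± 0.60 (SD, n = 3) (adjusted p = 0.000683). With it rose the immediate early genes Jun (2.86, adjusted p = 0.0364) and Btg2 (2.57, adjusted p = 0.0225), 8 of 27 in all, and Zc3h12a, an RNase that limits inflammatory transcripts (4.85 ± 0.61, adjusted p = 0.00683). The list of immediate early genes includes Socs3 and covers tissue dissociation too. A response to the handling of the digested glands was not told apart from a drug response.

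Cell type markers and signalling genes changed with AzaC as well. Kit, the receptor tyrosine kinase of luminal progenitors, rose from 7.26 ± 0.11 (SD, n = 2) to 11.39 ± 0.54 (SD, n = 3) (change 4.14 ± 0.90 SE, adjusted p = 0.0234). The retinal dehydrogenase Aldh1a3 rose by 4.68 (adjusted p = 0.0433) and the lipopolysaccharide receptor Cd14 by 3.71 (adjusted p = 0.0193). The cytokine Tgfb3 rose by 3.63 ± 0.80 (SE, adjusted p = 0.0251), the TGF-beta binding protein Ltbp1 by 2.69 (adjusted p = 0.0159), and the endothelial genes Cldn5 and Aqp1 by 1.80 and 1.72. The deacetylase genes Hdac5 and Sirt2 rose by 1.51 (adjusted p = 0.0121) and 1.40. Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, fell by 1.47 ± 0.18 (SE, adjusted p = 0.00620) and the respiratory chain genes Uqcrq and Cycs fell by 1.40 and 1.19. The calcium pump of milk secretion, Atp2b2, fell by 3.54 ± 0.74 (SE, adjusted p = 0.0221). Csn2 differed by 0.11 (adjusted p = 0.655), Wap by 0.38 (adjusted p = 0.171) and Lalba by 0.11 (adjusted p = 0.651), but these 3 stood at the top of the scale, where a change may not register. With the mean of all probe sets of a gene, the rise of Angptl4 was 2.95 (adjusted p = 0.0245), and Fdps (0.106), Acadl (0.129) and Uqcrq (0.0741) lost their calls. Aqp1 lost its call without pregnant PBS replicate 1 (change 1.07, adjusted p = 0.262). Dnmt1 differed by -0.07 (adjusted p = 0.861) and Hdac1 by -0.34 (adjusted p = 0.373).

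Camera called 17 lists in this comparison, of which 0 held with an estimated correlation, and the same was true of all 142 list calls over the 11 comparisons. Lower with AzaC were the cell cycle (median -1.41, adjusted p = 2.56e-15, 0.397 estimated), oxidative phosphorylation (-0.65, 8 of 39 fell, adjusted p = 2.5e-12, 0.397 estimated), cholesterol synthesis (-1.25, adjusted p = 6.71e-10, 0.362 estimated) and fatty acid and triglyceride synthesis (-1.0, adjusted p = 1.14e-07, 0.301 estimated). The unfolded protein response (-0.47, 5 of 25 fell, adjusted p = 0.00553) and ribosomal proteins (-0.16, adjusted p = 0.0368) were also lower. Adjusted over the list alone, 32 cell cycle, 15 cholesterol and 22 oxidative phosphorylation genes fell. Higher were immediate early genes (1.16, adjusted p = 2.45e-06, 0.397 estimated), endothelial markers (0.76, adjusted p = 4.73e-05), fatty acid oxidation (0.52, adjusted p = 0.00016) and luminal progenitor markers (0.55, 5 of 17 rose, adjusted p = 0.000435). Deacetylases and acetyltransferases (0.42, 3 of 23 rose), macrophage markers (0.61), extracellular matrix (0.50), TGF-beta and Wnt genes (0.47, 3 of 33 rose), interferon-stimulated genes (0.44), luminal epithelium (0.37) and fibroblasts (0.65) were also called higher (adjusted p from 0.00431 to 0.00828). In the interferon list the only member past the threshold, Ifi35, fell by 1.17. Imprinted genes (0 of 27 passed, adjusted p = 0.984), germline genes (0.324), the DNA methylation machinery (2 of 15 rose and 2 fell; 0.837) and milk and secretory genes (7 of 27 fell; median -0.06, mean -0.45; 0.0544) were not called. For the other called lists the adjusted p with an estimated correlation lay between 0.397 and 0.635. The number of genes past the threshold was 16 without pregnant PBS replicate 1, 14 without replicate 2, 177 without pregnant AzaC replicate 1, 138 without replicate 3 and 0 when only these 5 arrays were fitted. Socs3 kept its call without each of the 5 arrays compared (adjusted p up to 0.0173; 0.0609 with these 5 arrays only). List calls that ended were macrophages (0.0738) and luminal epithelium (0.0511) without pregnant PBS replicate 2, and fibroblasts without pregnant AzaC replicate 3 (0.0648). The call for ribosomal proteins ended without either PBS array (0.0814 and 0.0509), without pregnant AzaC replicate 2 (0.0665) or 3 (0.0655) and after quantile normalization (0.114).

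**Figure D2:**
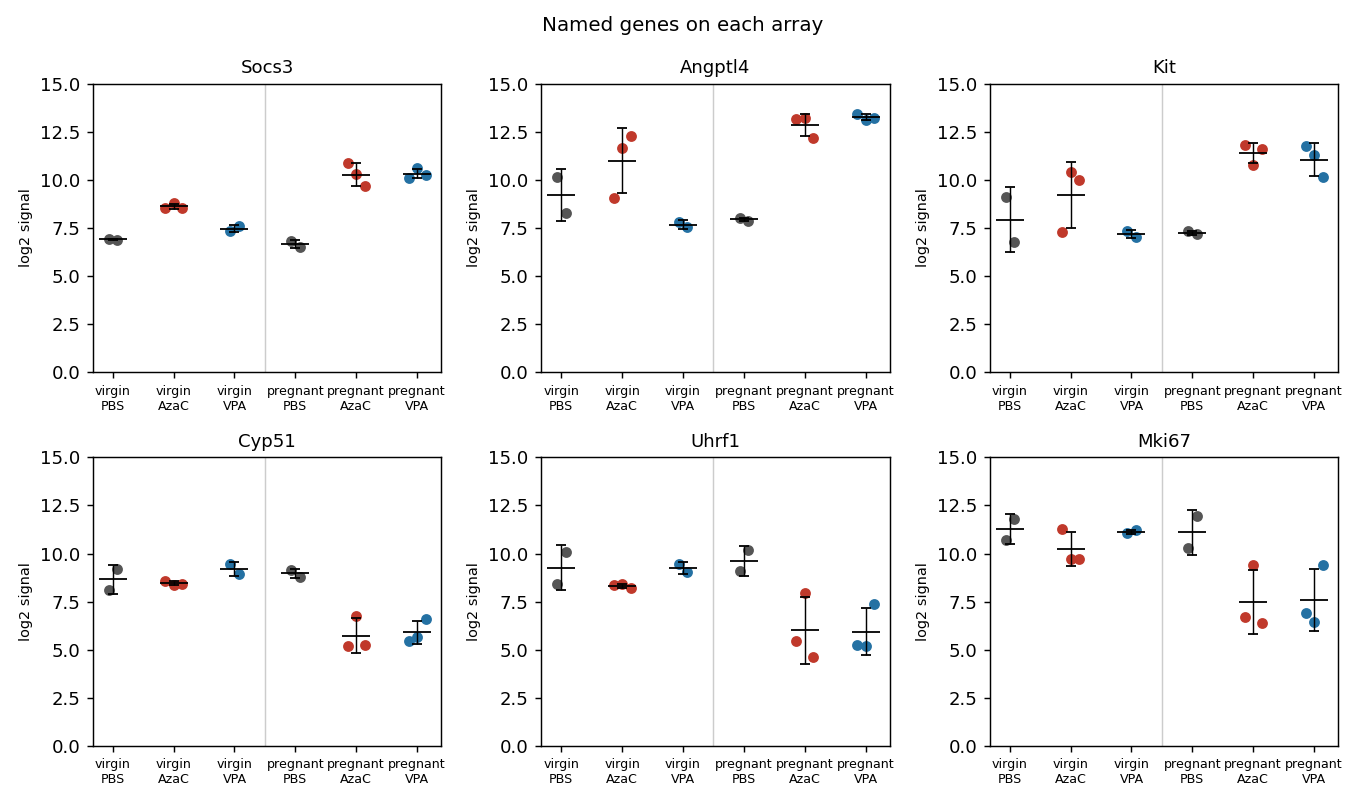
Log2 signal of 6 genes on each array (points), by stage label and injection, with group means and SD (bars). With AzaC and VPA in arrays labelled pregnant, Socs3 reads 10.27 and 10.32 against 6.66 with PBS, and Cyp51 reads 5.73 and 5.90 against 8.96.

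With VPA in arrays labelled pregnant, 741 genes differed from PBS, 451 up and 290 down. Angptl4 rose by 5.31 ± 0.80 (SE, adjusted p = 0.0108), the neuronal tubulin Tubb2b by 5.53 ± 1.01 (adjusted p = 0.0175) and the stress-related transcription factor Nfe2l3 by 4.61 ± 0.86 (adjusted p = 0.0190). Socs3 rose by 3.66 ± 0.29 (SE), from 6.66 ± 0.19 (SD, n = 2) to 10.32 ± 0.25 (SD, n = 3) (adjusted p = 0.000602), and Kit by 3.79 (adjusted p = 0.0359). Phactr1, a regulator of actin and of protein phosphatase, fell by 4.2 ± 0.46 (SE, adjusted p = 0.00411), from 6.99 ± 0.42 (SD, n = 2) to 2.79 ± 0.21 (SD, n = 3). The kinetochore gene Cenph fell by 4.65 ± 0.78 (adjusted p = 0.0130), Uhrf1 by 3.69 (adjusted p = 0.0404) and the helicase gene Mcm5 by 2.27 (adjusted p = 0.0190). Lipid genes split as with AzaC: Cyp51 fell by 3.06, Scd2 by 2.77 (adjusted p = 0.0205) and the fatty acid synthase Fasn by 1.5, while Acadl and Ucp3 rose by 2.60 and 2.56 (adjusted p = 0.0108). With values under 5 set to 5, the fall of Phactr1 was 1.99 (adjusted p = 0.0156) and that of Cenph 1.18 (adjusted p = 0.0939). With the mean of all probe sets Angptl4 rose by 3.06 and Acadl lost its call (0.0935). Of secretory genes, Atp2b2 fell by 3.95 (adjusted p = 0.0190) and the phosphate and zinc transporters Slc34a2 and Slc30a4 by 1.23 and 0.86. Csn2, at the top of the scale, where a change may not register, differed by 0.23 (adjusted p = 0.333). Dcn, a collagen-binding proteoglycan of fibroblasts, rose by 1.37 (adjusted p = 0.0499; 0.0521 after quantile normalization), Dnmt1 differed by -0.03 and Hdac1 by -0.20.

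Camera called 17 lists for VPA in these arrays. The cell cycle (median -1.41, 11 of 43 fell, adjusted p = 2.48e-19, 0.363 estimated), cholesterol synthesis (-1.55, 8 of 19 fell, adjusted p = 1.95e-10, 0.306 estimated), fatty acid and triglyceride synthesis (-0.95, 7 of 24 fell, adjusted p = 1.86e-07, 0.306 estimated) and oxidative phosphorylation (-0.24, 0 of 39 passed, adjusted p = 0.000686) were lower. So were milk and secretory genes (-0.17, 3 of 27 fell, adjusted p = 0.0124) and the unfolded protein response (-0.34, 1 of 25 fell, adjusted p = 0.0149). Fatty acid oxidation (0.92, 7 of 23 rose, adjusted p = 6.01e-10, 0.356 estimated), fibroblasts (0.96, 1 of 17 rose, adjusted p = 2.72e-05), immediate early genes (1.02, 5 of 27 rose, adjusted p = 0.00019), macrophages (0.83, 1 of 21 rose, adjusted p = 0.000415) and luminal epithelium (0.60, 2 of 20 rose, adjusted p = 0.00119) were higher. Adjusted over the list alone, 36 cell cycle genes fell and 14 fatty acid oxidation genes rose. Extracellular matrix (0.59), endothelial cells (0.64), skeletal muscle (1.09, 0 of 18 passed), luminal progenitors (0.48, 4 of 17 rose), deacetylases and acetyltransferases (0.49) and TGF-beta and Wnt genes (0.42, 5 of 33 rose) completed the higher lists (adjusted p from 0.000779 to 0.0149). None of the 17 calls held with an estimated correlation (adjusted p from 0.306 to 0.638). Leaving out pregnant PBS replicate 1 left 24 genes and leaving out replicate 2 left 20, and 214, 193 and 231 passed without pregnant VPA replicate 1, 2 and 3. Socs3 passed under all 15 alternatives run for it and Phactr1 under 14 (adjusted p up to 0.0199 and 0.0432). Leaving out the dimmest genes removes Phactr1 and is not among them. List calls ended for milk genes without pregnant PBS replicate 1 (0.128), pregnant VPA replicate 3 (0.133) or the 3 arrays of highest 3' bias (0.202), endothelial cells without pregnant PBS replicate 1 (0.0678), and skeletal muscle without pregnant PBS replicate 2 (0.612). They also ended for TGF-beta and Wnt genes without pregnant PBS replicate 2 (0.0591) or pregnant VPA replicate 1 (0.0749), extracellular matrix without pregnant VPA replicate 1 (0.0666), and luminal progenitors without the dimmest genes (0.0586).

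**Figure D3:**
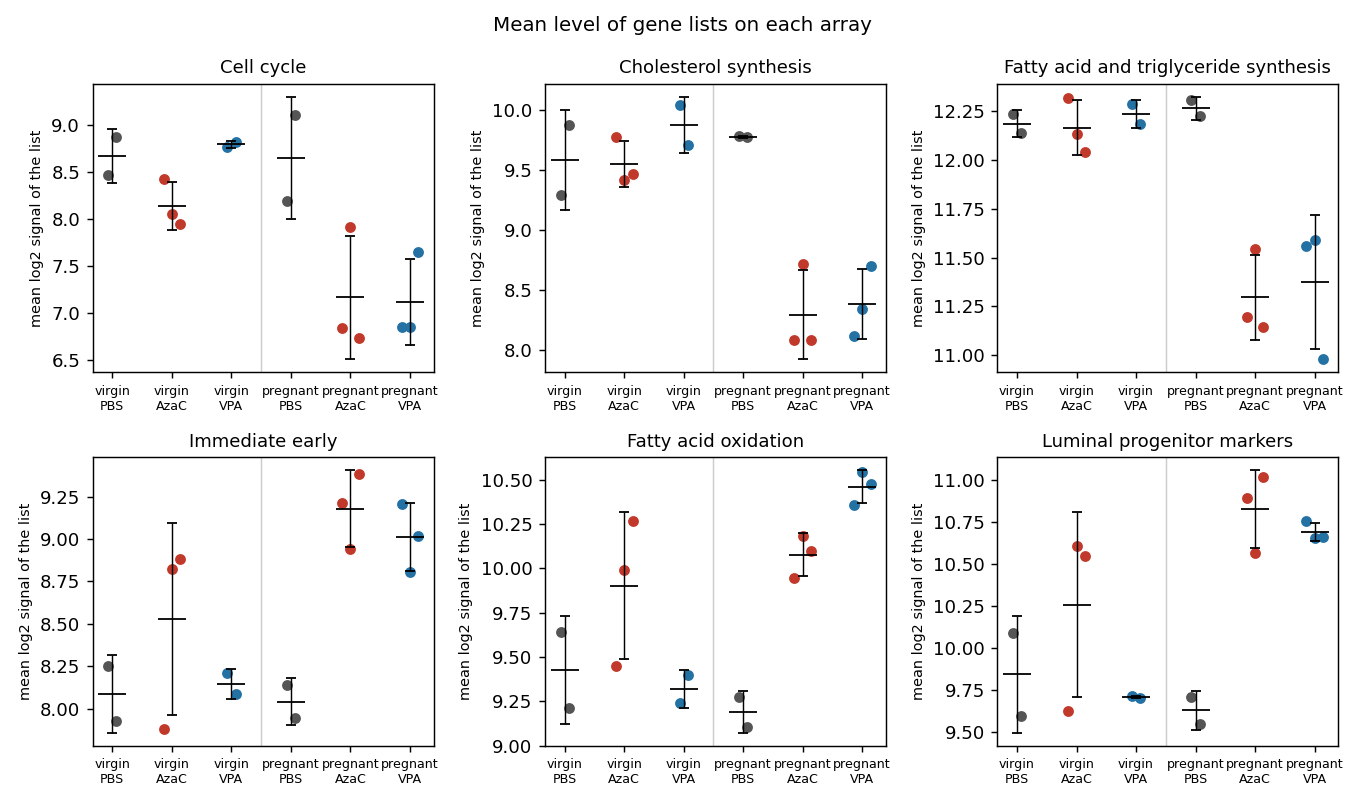
Mean log2 signal of the members of 6 gene lists on each array (points), by stage label and injection, with group means and SD (bars). In arrays labelled pregnant the cholesterol synthesis mean lies at 9.77 and 9.78 with PBS and between 8.08 and 8.72 with AzaC or VPA.

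Whether a drug acted differently in the arrays of the 2 stages was tested as the difference between its fold changes. For VPA, 39 genes passed, 15 with a higher and 24 with a lower change with the pregnant label. Socs3 differed by 3.11 ± 0.43 (SE, adjusted p = 0.0279), Angptl4 by 6.84 ± 1.18 (adjusted p = 0.0483), Ucp3 by 3.66 ± 0.57 (adjusted p = 0.0325) and Trp53inp1, a stress protein induced by p53, by 3.93 (adjusted p = 0.0491). Phactr1 differed by -4.88 ± 0.69 (adjusted p = 0.0279), the cyclin Ccnd1 by -2.97 ± 0.46 (adjusted p = 0.0325) and Bhlha15, a transcription factor of secretory cells, by -2.63 (adjusted p = 0.0325). For AzaC no gene passed with limma (0 of 12393, 1587 with an unadjusted p under 0.05; 1 gene when only the arrays compared were fitted and 24 with a floor at 5). The smallest p-values belonged among others to the glucose transporter Slc2a1 (-1.29), the cell cycle factor Tfdp1 (-1.36) and the lymphatic growth factor Vegfd (1.22), all with an adjusted p of 0.124, and Socs3 differed by 1.91 (adjusted p = 0.137). Cholesterol synthesis had a median difference of -1.33 for AzaC (adjusted p = 1.56e-08, 0.324 with an estimated correlation) and -1.88 for VPA (adjusted p = 2e-09; 0.446 estimated). The cell cycle had medians of -0.92 (adjusted p = 2.54e-06; 0.5 estimated) and -1.64 (adjusted p = 1.56e-13; 0.453 estimated), and oxidative phosphorylation had -0.69 (adjusted p = 5.95e-11; 0.477 estimated) and -0.50 (adjusted p = 3.61e-06; 0.49 estimated). At a floor of 5 the Phactr1 difference was -2.67 (adjusted p = 0.0456, up to 0.138 over its alternatives). With the mean of all probe sets that of Angptl4 was 4.22 (0.0669) and that of Bhlha15 -1.49 (0.0623). Every one of the VPA genes named here lost its call without at least 1 array. Counts were 2 and 3 without pregnant PBS replicate 1 and 2, 0, 0 and 5 without pregnant VPA replicate 1, 2 and 3. They were 80 without virgin PBS replicate 2, and 0 and 10 without virgin VPA replicate 1 and 2. For AzaC, counts were 15 without virgin PBS replicate 1, 42 without pregnant AzaC replicate 2, 1 without pregnant PBS replicate 2 and 1 without pregnant AzaC replicate 1.

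The stage comparison within AzaC asks what differed between pregnant and virgin labels when both had received the inhibitor. Sterol genes fell: Cyp51 by 2.72 ± 0.44 (SE, adjusted p = 0.0265), Idi1 by 2.54 ± 0.39 (adjusted p = 0.0243) and Fdps by 2.42. Olah, the thioesterase that ends fatty acid chains for milk, fell by 1.94 ± 0.26 (SE, adjusted p = 0.0229), from 12.80 ± 0.27 (SD, n = 3) to 10.86 ± 0.47 (SD, n = 3), the desaturase Fads1 by 1.43 (adjusted p = 0.0243) and G0s2, an inhibitor of fat breakdown, by 2.51 (adjusted p = 0.0325). Socs3 rose by 1.66 ± 0.26 (SE, adjusted p = 0.0243) and the opioid receptor gene Oprk1 by 2.74 (adjusted p = 0.0409). In total 15 genes rose and 137 fell. Among the lists, 5 of 19 cholesterol synthesis genes fell (median -1.10, adjusted p = 4.69e-11, 0.266 estimated), as did 4 of 24 fatty acid and triglyceride genes (-0.94, adjusted p = 1.32e-09, 0.155 estimated) and 3 of 27 milk and secretory genes (-0.11, adjusted p = 0.00106, 0.598 estimated). Oxidative phosphorylation had a median of -0.58 with 0 of 39 past the threshold and 27 of them adjusted over the list alone (adjusted p = 4.57e-14, 0.394 estimated). Skeletal muscle markers were higher (0.83, 0 of 18 passed, adjusted p = 0.00112, 0.708 estimated), a call that ended without pregnant AzaC replicate 3 (0.0886) or virgin AzaC replicate 1 (0.141). Oprk1 lost its call at a floor of 5 (change 0.0033, adjusted p = 1), as did Fdps with the mean of all probe sets (-1.19, adjusted p = 0.268). The count of 152 became 4 after quantile normalization and 2 when only these arrays were fitted. It was 5 and 7 without pregnant AzaC replicate 1 and 3, 501 without pregnant AzaC replicate 2, and 0, 4 and 5 without virgin AzaC replicate 1, 2 and 3.

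The stage comparison within VPA had 458 genes higher and 367 lower in arrays labelled pregnant. Angptl4 rose by 5.58 ± 0.80 (SE, adjusted p = 0.0135), Kit by 3.88 (adjusted p = 0.0318), Pdk4, which slows pyruvate oxidation, by 3.08 and Socs3 by 2.86 ± 0.29 (SE, adjusted p = 0.00511). Fibroblast genes rose, among them Pi16 by 2.79, Mfap5 by 2.05 and Col3a1, a fibrillar collagen, by 1.51, 4 of 17 in all (median 1.39, adjusted p = 2.18e-07, 0.556 estimated). Phactr1 fell by 4.31 ± 0.46 (SE, adjusted p = 0.00511), Cenph by 4.83 (adjusted p = 0.0148) and the mitotic kinase Cdk1 by 3.16 (adjusted p = 0.0481), and 15 of 43 cell cycle genes fell (median -1.66, adjusted p = 4.96e-20, 0.451 estimated). In cholesterol synthesis 9 of 19 genes fell (median -1.62, adjusted p = 1.81e-11, 0.243 estimated). Bpifa2, a salivary gland secretory protein, fell by 5.71 (adjusted p = 0.0361), from 10.27 ± 3.43 (SD, n = 2) in arrays labelled virgin, and lost its call without virgin VPA replicate 2 (change -3.28, adjusted p = 0.228), as did Pi16 (1.71, 0.266) and Col3a1 (0.99, 0.246). With the mean of all probe sets Pi16 was at 1.62 (0.0897) and Col3a1 at 0.80 (0.0736). Counts were 183, 258 and 249 without pregnant VPA replicate 1, 2 and 3, and 4 and 52 without virgin VPA replicate 1 and 2. Socs3 and Phactr1 lost their calls without virgin VPA replicate 1 (0.0533 and 0.0572). At a floor of 5 the fall of Phactr1 was 2.1 (0.0140) and that of Cenph 1.36 (0.0590).

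Direct comparison of the inhibitors asks whether AzaC and VPA changed different genes. In arrays labelled pregnant, Socs3 differed between AzaC and VPA by -0.04 (95% confidence interval -0.61 to 0.52), Cyp51 by -0.17 (-1.15 to 0.80) and Angptl4 by -0.40 (-1.96 to 1.16). Lgals1, a lectin, was at -0.89 and the bone transcription factor gene Sp7 at 2.84, neither past the threshold. No gene passed with limma at either stage (0 and 0; 468 and 813 genes with an unadjusted p under 0.05 in arrays labelled pregnant and virgin; 1 in the latter when only the arrays compared were fitted). Oxidative phosphorylation was lower with AzaC than with VPA in arrays labelled pregnant (median -0.43, 0 of 39 passed, adjusted p = 1.1e-15, 0.552 estimated), as was fatty acid oxidation (-0.40, adjusted p = 4.32e-07, 0.668 estimated). Skeletal muscle markers were lower in the same comparison (-0.49, 0 of 18 passed, adjusted p = 0.0424, 0.893 estimated), a call that ended without pregnant AzaC replicate 1 (-0.0042, 0.719), where their mean read 10.8 against 12.0 and 12.5 on replicates 2 and 3 and 12.2 to 12.4 with VPA. In arrays labelled virgin, cell cycle genes were lower with AzaC than with VPA (-0.73, 0 of 43 passed, adjusted p = 1.49e-09, 0.802 estimated), and fatty acid oxidation genes were higher (0.29, adjusted p = 0.000106, 0.802 estimated). Muscle markers were lower there too (-0.72, adjusted p = 0.000585, 0.861 estimated), but not called without virgin AzaC replicate 1 (-0.06, 0.20) or virgin VPA replicate 2 (-0.39, 0.234). Without virgin VPA replicate 2, 17 genes passed in arrays labelled virgin, and 1 passed without virgin AzaC replicate 3. In arrays labelled pregnant 1 passed without pregnant AzaC replicate 1 or 3 or pregnant VPA replicate 1, and 2 without pregnant VPA replicate 3 or without the 3 arrays of highest 3' bias.

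The fold changes of AzaC and VPA in arrays labelled pregnant correlated at r = 0.869 (rho = 0.844) across genes, which are not independent replicates, among 9 pairs of comparisons examined. Of the called genes, 325 rose and 244 fell with both drugs, Socs3, Angptl4, Kit, Cyp51 and Uhrf1 among them, where 17.0 and 11 were expected from independent calls, and 0 went in opposite directions. The counts expected from independent calls do not allow for the 2 PBS arrays that both drugs use. Because of these arrays, a correlation of 0.601 arose in simulated tables without any drug effect. Shared calls numbered 0 there, but tables without effects yield hardly any calls, so this is no measure of the sharing to be expected. Genes varied independently in these tables. How far genes that vary together could raise the correlation or the shared calls was not simulated. The covariance was 0.462, against 0.131 in the simulated tables. In arrays labelled virgin the correlation was 0.561, against 0.547 in the simulated tables, and the covariance 0.159 against 0.130. Across the stages, without a shared array, AzaC in virgin and VPA in pregnant correlated at 0.252 (-0.00080 in the simulated tables). The sign was the same for 79.4% of the 741 genes called with VPA in pregnant and for 60.8% of all genes (50.1% in the simulated tables). AzaC in pregnant and VPA in virgin correlated at -0.129 (-3.41e-05 in the simulated tables), and 24.4% of the 938 genes called with AzaC in pregnant had the same sign with VPA in virgin. The correlation was 0.231 between AzaC at the 2 stages and -0.0695 between VPA at the 2 stages.

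**Figure D4:**
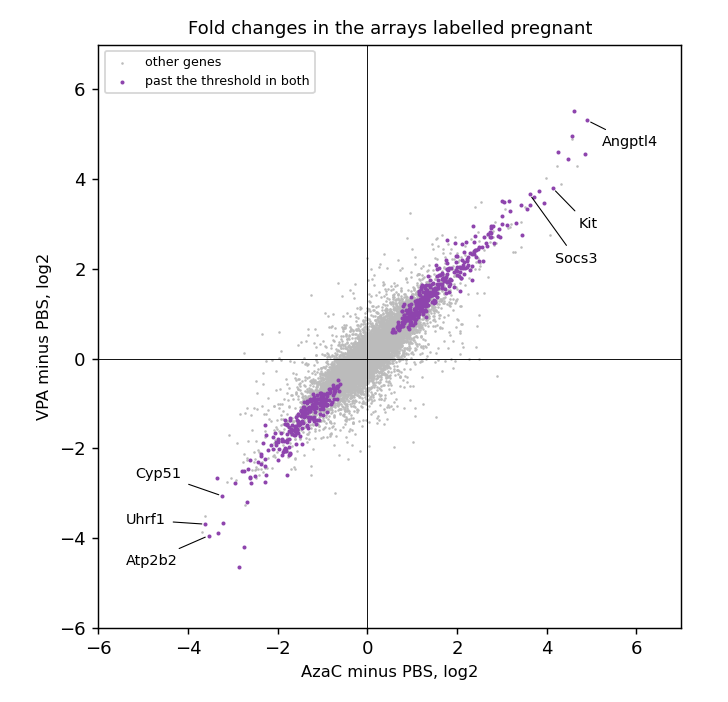
Log2 fold change with VPA (vertical axis) against that with AzaC (horizontal axis) in arrays labelled pregnant, with a point per gene and purple points past the threshold in both. The points follow the diagonal (r = 0.869 across genes) over a range in which Angptl4 rose by 4.91 and 5.31 and Atp2b2 fell by 3.54 and 3.95.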

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

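Every test in this part was chosen after the result was seen, except the tests of drug effects between stages and the correlations of one drug in virgin with the other in pregnant.

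In arrays labelled pregnant, the same genes differed from PBS in the same direction with AzaC and VPA, with 325 rises and 244 falls shared. Without a shared array, AzaC in virgin and VPA in pregnant correlated at 0.252, and AzaC in pregnant and VPA in virgin at -0.129. Simulated tables, in which genes varied independently, gave values near 0. The pregnant-minus-virgin changes of the AzaC arrays and of the VPA arrays have no array in common. They still correlated at 0.607 across genes (covariance 0.251, against -0.0284 and -0.0465 of each with that of the PBS arrays). The drug arrays labelled pregnant thus shared a difference from virgin arrays that does not come from the shared PBS arrays. Whether it is a drug effect cannot be told, because a stage difference that the 2 pregnant PBS arrays lacked would give it too. Those PBS arrays lay among the arrays labelled virgin on the first principal component (-28.2 and -32.1) and stay open as a source. With the 3' to 5' covariate for RNA quality, 100% of the AzaC calls kept their sign and at least 50% of their fold change. This does not decide on RNA quality, because the compared groups had similar averages of the covariate, which could therefore move the fold changes little. In arrays labelled pregnant the Gapdh difference was 0.09 and 0.47 with PBS and 0.85, -0.12 and 0.20 with AzaC. An axis on which replicates of a group also differ carried 35.9% of the within-group variance and correlated at 0.391 with the AzaC fold changes. Among the arrays of highest 3' bias, virgin PBS replicate 2 scored -25.7 on it and pregnant VPA replicate 3 scored -25.1. In a group of 2 arrays the scores mirror each other, so virgin PBS replicate 1, with the highest salivary transcripts, scored 25.7. Which of these 2 PBS arrays sets the score cannot be told. Pregnant AzaC replicate 1, also of high 3' bias, scored -13.6, and virgin AzaC replicate 1, with a Gapdh difference of 0.07, scored -15.4. The axis may thus hold RNA quality in part. Drawn only from groups outside this comparison, the axis correlated at 0.441 in size with the AzaC fold changes. It stays open as a part of the pattern, as does a response that both inhibitors share. Of such responses only a likeness to that of stopped milk removal was tested, without a decision. The mix of cells was not tested as an explanation, and the labels do not say whether PBS and drug arrays were processed together.

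Milk-protein transcripts stood at the top of the scale in arrays labelled virgin as well as in those labelled pregnant. A single mislabelled array is excluded, since Csn2 lay in the top 1% of genes on 7 of 7 arrays labelled virgin. Saturated probe sets could hide a stage difference. Against this only genes with a mean under 13 can speak, and most of these 25 milk and lipid synthesis genes belong to lipid synthesis. Their median difference between the labels with PBS was 0.12 (SD 0.28, range -0.57 to 0.65). The 20 of 27 milk and secretory genes with a mean over 13 are not among them, so a difference hidden in those stays untested. It remains possible that the stage label names the time of injection while the glands were collected late, and 0 samples carry a label for the stage of collection that would settle it. A stage difference in biology was tested only as the labels state it.

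Salivary transcripts were high on 3 arrays labelled virgin, on PBS replicate 2 for some genes only, and highest on PBS replicate 1. On the latter Bpifa2 read 13.79, Smr3a 13.08, Amy1 13.01, Dnase1 12.51 and Cst10 12.09. In the same order they read 12.69, 10.55, 10.04, 9.54 and 9.15 on virgin VPA replicate 2. On virgin PBS replicate 2 Bpifa2 read 10.01 and Smr3a 8.61, against at most 7.84 and 5.05 on the other arrays. Amy1, Dnase1 and Cst10 read 7.54, 7.96 and 7.56 on virgin PBS replicate 2, against at most 7.48, 6.82 and 7.33 on the other arrays. Salivary gland tissue in the preparation of virgin PBS replicate 1 is a candidate explanation. The 5 genes noticed first, Smr3a, Bpifa2, Amy1, Dnase1 and Pip, were left out of its test, while Cst10 was kept. Of the 15 other measured salivary genes, 7 had their highest value on that array, 3 of them by more than 1. The 10000 random lists matched on mean expression had 0.67 on average, and 0% of them had as many. Genes of one tissue are not independent, and the list was written after several values had been seen. Lpo, Smr2, Egf, Car6, Mucl1, Mucl2, Bpifb1 and Bpifa1 had their highest value on other arrays. Digestion of the gland, the only purification in the labels, would not remove such tissue, and no biological explanation was tested.

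A test of the difference between stages set apart 39 genes for VPA. The differences of the named ones were 6.84 for Angptl4, 4.46 for Cxadr, 4.40 for Fads3, 3.93 for Trp53inp1, 3.66 for Ucp3 and 3.11 for Socs3, and, in the other direction, -4.88 for Phactr1, -4.02 for Il18bp, -2.97 for Ccnd1, -2.95 for Il15, -2.63 for Bhlha15, -2.63 for Slc13a1 and -1.57 for Sdf2l1. With the mean of all probe sets of a gene, Cxadr was at 2.13 (adjusted p = 0.0574) and Fads3 at 2.86 (adjusted p = 0.132), both without a call, and at a floor of 5 Il18bp was at -2.31 (adjusted p = 0.0456). Among lists, the median difference for VPA was -1.88 for cholesterol synthesis, -1.64 for the cell cycle, -1.03 for fatty acid and triglyceride synthesis, -0.55 for the unfolded protein response, -0.50 for oxidative phosphorylation and -0.18 for milk and secretory genes. It was 1.67 for fibroblasts, 1.07 for immediate early genes, 0.86 for fatty acid oxidation, 0.83 for adipocytes, 0.83 for extracellular matrix, 0.81 for macrophages, 0.75 for luminal progenitors, 0.69 for interferon-stimulated genes, 0.63 for endothelial cells and 0.57 for TGF-beta and Wnt genes. For AzaC the list medians were -1.33 for cholesterol synthesis, -1.19 for fatty acid and triglyceride synthesis, -0.92 for the cell cycle, -0.69 for oxidative phosphorylation, -0.61 for the unfolded protein response, -0.36 for ribosomal proteins and -0.16 for milk and secretory genes. They were 0.83 for fibroblasts, 0.80 for skeletal muscle, 0.77 for immediate early genes, 0.63 for adipocytes, 0.63 for endothelial cells, 0.62 for extracellular matrix, 0.58 for interferon-stimulated genes, 0.44 for macrophages, 0.38 for TGF-beta and Wnt genes and 0.20 for luminal progenitors. None of these list calls held with an estimated correlation. Without virgin PBS replicate 1, the array with the highest salivary transcripts, the calls for immediate early genes (0.0693 for AzaC and 0.0668 for VPA), adipocytes (0.747 and 0.430) and macrophages (0.353 and 0.0798) were among those that ended. Without virgin VPA replicate 2, which also carried them, 10 genes passed for VPA and the call for endothelial cells ended (0.134).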

How the results depend on the processing

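The RNA quality covariate, the set without the 3 arrays of highest 3' bias and the floor at 5 were chosen after the data were seen, and the other settings were planned.

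Counts of genes past the threshold moved by more than 1.5 times as follows, and the cause was not tested. Quantile normalization gave 16 genes for the VPA difference between stages and 4 for the stage within AzaC. Leaving out the dimmest genes gave 0 for the stage with PBS, 0 for VPA in virgin, 1434 for AzaC in pregnant, 1149 for VPA in pregnant, 257 for the VPA difference and 368 for the stage within AzaC. Trend and robust settings gave 0 for the stage with PBS, 0 for VPA in virgin, 242 for the VPA difference and 271 for the stage within AzaC. Fitting only the arrays compared gave 0 for the stage with PBS, 0 for AzaC in pregnant, 0 for VPA in virgin, 364 for VPA in pregnant, 1 for the AzaC difference, 84 for the VPA difference, 2 for the stage within AzaC, 421 for the stage within VPA and 1 for AzaC against VPA in virgin. The replicate block gave 0 for the stage with PBS, 466 for AzaC in pregnant, 0 for VPA in virgin, 241 for VPA in pregnant, 0 for the VPA difference, 64 for the stage within AzaC and 239 for the stage within VPA.

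The RNA quality covariate gave 2 for the stage with PBS, 1578 for AzaC in pregnant, 1300 for VPA in pregnant, 200 for the VPA difference, 447 for the stage within AzaC and 1425 for the stage within VPA. Without the 3 arrays of highest 3' bias the counts were 3 for the stage with PBS, 448 for AzaC in pregnant, 0 for VPA in virgin, 247 for VPA in pregnant, 92 for the VPA difference, 0 for the stage within AzaC, 242 for the stage within VPA and 2 for AzaC against VPA in pregnant. The floor at 5 gave 0 for the stage with PBS, 0 for VPA in virgin, 1149 for VPA in pregnant, 24 for the AzaC difference, 275 for the VPA difference and 339 for the stage within AzaC.

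Leaving out each array in turn gave 1 to 22 genes for the stage with PBS, 0 to 33 for AzaC in virgin, 14 to 1335 for AzaC in pregnant, 0 to 39 for VPA in virgin, 20 to 231 for VPA in pregnant, 0 to 42 for the AzaC difference, 0 to 80 for the VPA difference, 0 to 501 for the stage within AzaC, 4 to 258 for the stage within VPA, 0 to 17 for AzaC against VPA in virgin and 0 to 2 in pregnant. Where a single PBS or virgin VPA array was left, it was assumed to vary like the other groups.

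Of 164 named-gene results past the threshold, 0 reversed under any setting and 2, Socs3 and Phactr1 for VPA in pregnant, lost their call in none of the 15 and 14 alternatives run for them. Of 142 list calls, 0 held with an estimated correlation. Medians of called lists changed sign without the 3 arrays of highest 3' bias for milk genes in the VPA difference (0.03) and in the stage within VPA (0.04) and for skeletal muscle in AzaC against VPA in pregnant (0.01), and with the covariate for polycomb targets in that comparison (-0.00037), with no call left in each case. The correlation of AzaC and VPA fold changes across genes lay between 0.801 and 0.894 in pregnant and between 0.476 and 0.785 in virgin when arrays were left out. Simulated tables without effects gave 0.544 to 0.550 in pregnant and 0.449 to 0.503 in virgin without a drug array, and 0.751 to 0.752 and 0.705 without a PBS array, where the observed values were 0.886 to 0.894 and 0.659 to 0.785. Among pairs without a shared array it was 0.252 for AzaC in virgin with VPA in pregnant and -0.129 for AzaC in pregnant with VPA in virgin, with 0.410 and -0.293 without the dimmest genes. Without these genes it was 0.937 in pregnant and 0.460 in virgin, against 0.602 and 0.545 in simulated tables. Genes near the floor limit what can be seen: 758 genes were listed at 0 on at least 1 array, Mst1r among them. Pseudocounts were not run, since the values are on a log scale.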

Other observations

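All tests in this part were chosen after the result was seen, except the splits of the arrays and the fits of single genes and of the lists fixed in advance, and the genes in the next paragraph were chosen after their values were seen.

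Several single genes changed in both drug groups of the arrays labelled pregnant without a call for their lists, the DNA methylation machinery (adjusted p = 0.837 with AzaC and 0.925 with VPA) and p53 targets (0.257 and 0.366). Hells, a chromatin remodeller needed for DNA methylation, fell by 2.59 with AzaC (adjusted p = 0.0180) and by 2.78 with VPA (adjusted p = 0.0186). Gadd45a, a stress protein linked to DNA demethylation, rose by 3.42 (adjusted p = 0.0309) and 3.43 (adjusted p = 0.0360), and Gadd45b rose by 1.48 (adjusted p = 0.0262) and 1.56 (adjusted p = 0.0255). Trp53inp1 rose by 3.12 (adjusted p = 0.010) and 2.98 (adjusted p = 0.0116). The progenitor keratin Krt15 fell by 2.29 (adjusted p = 0.0120) and 1.49 (adjusted p = 0.0476), and Cited1, a coactivator of hormone-sensing cells, fell by 2.06 (adjusted p = 0.0221) and 1.66 (adjusted p = 0.0475). Of imprinted genes, Grb10 rose by 0.98 (adjusted p = 0.0497) and Impact fell by 0.92 (adjusted p = 0.0460) with VPA.

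Socs3, Stat3, Osmr, Tgfb3 and Cd14 are known to rise when milk removal stops, so a response like that of involution may accompany both drugs. A list of 30 involution genes holds 4 of these, which raised the idea and were left out of its test. The other 26, of which 4 also belong to other lists, had a median change of 0.51 with AzaC (adjusted p = 0.00823) and 0.74 with VPA (adjusted p = 0.00823) in arrays labelled pregnant, by camera adjusted over 5 comparisons. With an estimated correlation the adjusted p was 0.590 for both, so the test leaves the explanation open. Of the 26, 0 rose and 1, Orm1, fell by 1.12 (adjusted p = 0.0482) with AzaC, and 1, Cebpd, rose by 1.83 (adjusted p = 0.0392) and 0 fell with VPA.

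Skeletal muscle transcripts were abundant on all arrays, with a mean of 18 marker genes between 9.80 and 12.5. Acta1, the skeletal actin, read from 11.82 to 14.20.

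The 6 AzaC arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The division by stage gave 152 genes, which 1 of 10 divisions, itself, reached, and the highest other gave 2. For AzaC against VPA in arrays labelled pregnant the 10 divisions are likewise too few. The real one gave 0 genes, which all 10 reached, and the highest other gave 1.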
